A study of Mus musculus with 16 samples.

How the data were processed

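Total RNA of the left lung of 16 mice was labelled with biotin and hybridised to Affymetrix mouse expression arrays, 1 array per mouse, per the labels. The authors deposited 1 intensity per probe set and array, made with RMA (robust multi-array averaging, which corrects background, normalizes between arrays and summarises the probes of a set) per the submitters' processing notes. The software and its version are not given in the sources used here. The deposited intensities were on a linear scale, from 11.1 to 26974.7, while log2 values had been foreseen for RMA, so their log2 was taken. Medians of the arrays differed by at most 0.076 log2, which is what normalization between arrays leaves, so a change of all RNA together would not be visible. No detection calls were used here, so how far a dim probe set stood above background is unknown. Of 22690 probe sets, 64 were controls and were left out, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. The annotation can be old, and no gene was named from a probe set with several. For each of 12393 genes the probe set with the highest mean over all arrays was tested, chosen without the groups, and 4956 genes had more than 1 probe set.

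Groups were taken from the genotype and exposure labels and sex from the labels of each mouse. All arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 scale, with the 4 groups and sex as terms, and with 8 groups of genotype, exposure and sex for the ozone by sex interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The Adipoq difference was tested by exact permutation. The 42 gene lists, of pathways and of markers of lung and other cell types, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with a correlation estimated from the residuals and limma's fry as alternatives. Fry tests whether a list's genes move, on balance, in one direction, without comparing them with other genes. The lists, the models, the alternatives and the rule for named genes were set before the data were examined. The rule took, for each comparison of exposure or genotype, the 10 genes with the largest rise and the 10 with the largest fall among those called whose groups did not overlap. It also took the 5 of smallest p where none was called, 4 members of each called list, 27 fixed genes, and 5 genes per direction for sex and its interaction with ozone. Unnamed and predicted genes were left out, and not every gene the rule took is printed. Ucp1, Cidec, Krt4 and the other markers given as levels per array were named after their values were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

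The method was tested on simulated data drawn with the spread of each of the 12393 genes, with 200 genes changed. At log2 changes of 0.5, 1, 1.5 and 2 it recovered 84, 96, 96 and 100% of the changed genes for ozone in wildtype mice, 74, 96, 98 and 100% for ozone in deficient mice, 82, 98, 100 and 100% for genotype in air, 88, 98, 98 and 100% for genotype in ozone, 46, 98, 96 and 98% for the interaction, 90, 100, 100 and 100% for sex and 50, 94, 94 and 96% for ozone by sex. Between 3.98% and 6.60% of the calls were false, and camera, tested on all but sex and ozone by sex, called the planted list and 0 of the unchanged lists. The simulated genes varied independently and the lists were random. The simulation therefore does not show how often camera calls unchanged lists whose genes vary together. Alternatives were another quantile normalization, a common median, the dimmest genes left out, the mean of all probe sets, every probe set on its own, an intensity trend with a robust prior, array weights, stricter thresholds, no sex term, the replicate numbers as a block, 8 groups, each sex alone, the arrays of the compared groups alone and each array left out in turn. Added after the data were seen were fits without 3 air arrays that carried markers of other tissues and without those and deficient ozone F2, and the genotype difference averaged over both exposures. Chromosomes of genes came from RefSeq's gene table for the assembly GRCm38.p6.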

Results

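Gene expression was measured on 16 microarrays, each hybridised with RNA from the left lung of 1 mouse. The mice were wildtype C57BL/6 mice or mice genetically deficient in adiponectin, a hormone secreted by fat cells, and breathed room air or 0.3 ppm ozone, an oxidant air pollutant, for 72 h. The 4 groups held 4 mice each, 2 males and 2 females, named M1, M2, F1 and F2 here, with a mean age of 14 weeks. The median intensity of the arrays lay between 146 and 154, and the number of arrays limits the precision of every difference. The first principal component took 44.4% of the variance and placed the air arrays between -20.77 and -15.86 and the ozone arrays between 12.81 and 24.76. The free description of wildtype ozone F1 named room air while its title, source and exposure fields named ozone. It was kept in the ozone group, and its position on that component was 17.58. Differences are log2 fold changes ± SE of the limma fit, with 4 arrays per group unless stated, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

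Adipoq, the gene of adiponectin, was lower in the deficient mice, at 6.68 ± 0.90 log2 intensity against 8.48 ± 1.35 in wildtype mice (SD, n = 8 each), a difference of -1.80 (two-sided exact permutation p = 0.00420). In ozone the difference was -1.82 and the groups did not overlap (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). In air it was -1.78 with overlapping groups (exact permutation p = 0.143). The values per array were 7.19, 8.05, 11.52 and 8.89 in wildtype air, 7.70, 7.77, 7.96 and 8.76 in wildtype ozone, 6.32, 6.43, 6.97 and 8.82 in deficient air, and 6.36, 6.14, 6.33 and 6.07 in deficient ozone, each in the order M1, M2, F1 and F2. The array labelled deficient air F2, at 8.82, lay within the wildtype range. It and wildtype air F1 also carried Ucp1, the uncoupling protein of brown fat, at 7.27 and 7.25 against 4.62 to 5.18 on the other 14 arrays. Cidec, a lipid droplet protein of fat cells, was 8.54 and 8.67 there against 5.25 to 6.40. These arrays and deficient air M2, which carried muscle and squamous markers, are called the 3 arrays with markers of other tissues, and fits without them were chosen after seeing the data. Which part of Adipoq was removed is not given in the sources used here, so it is open whether its probe set reads the deleted part.

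The effect of ozone in wildtype mice was taken first, against room air. Timp1, an inhibitor of matrix metalloproteinases, rose 7.99-fold (3.0 ± 0.16 log2, n = 4 per group, adjusted p = 1.35e-08). Tnc, the matrix glycoprotein tenascin C, rose by 2.86 ± 0.21, and Retnla, a secreted product of alternatively activated macrophages and airway epithelium, rose by 2.76 ± 0.16. The proliferation marker Mki67 rose by 2.58 ± 0.14, the mitotic kinase Cdk1 by 2.56 ± 0.14 and Birc5, the mitotic and survival protein survivin, by 2.50 ± 0.10 (adjusted p = 2.13e-09). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, Rrm2, a subunit of ribonucleotide reductase, and Top2a, a DNA topoisomerase, rose by 2.46 ± 0.12, 2.45 ± 0.12 and 2.42 ± 0.11. Sprr1a, a cornified envelope protein of squamous epithelium, had the largest rise, 3.76 ± 0.65, with a wide error, and stood at 9.36 on deficient air M2. Among the genes that fell, Acaa1b, a peroxisomal thiolase, fell by 2.03 ± 0.22, the nuclear noncoding RNA Malat1 by 1.98 ± 0.25, and Epas1, the hypoxia-inducible factor 2 alpha, by 1.75 ± 0.11 (adjusted p = 8.27e-08). Lrat, which esterifies retinol, Glp1r, the receptor of glucagon-like peptide 1, and Bmpr2, a receptor of bone morphogenetic proteins, fell by 1.85 ± 0.37, 1.52 ± 0.13 and 1.38 ± 0.11. Fbxo32, a ubiquitin ligase subunit, Atrx, a chromatin remodeller, and Kdm5a, a histone demethylase, fell by 1.57 ± 0.25, 1.49 ± 0.19 and 1.38 ± 0.20. Over all genes, 4546 of 12393 passed the threshold, 2432 higher and 2114 lower, of which 102 and 67 moved at least 2-fold. The split was 3021 higher and 1787 lower with each array shifted to a common median. It turned to 1753 higher and 1913 lower with the dimmest genes left out, 4111 higher and 4112 lower over single probe sets, 338 higher and 442 lower at a fold of at least 1.5 and 954 higher and 973 lower in females alone. Cyp2e1, a cytochrome P450 abundant in fat and liver, passed at -1.61 ± 0.58, adjusted p = 0.0416. For Cyp2e1, the call was lost without wildtype air M2 (adjusted p = 0.0747), wildtype air F1 (0.137, with a difference of -0.97), wildtype ozone M2 (0.0559), wildtype ozone F1 (0.127), wildtype ozone F2 (0.0674), deficient ozone M2 (0.0504) and deficient ozone F1 (0.0501), in a range of 0.0225 to 0.563 over the alternatives. The Cyp2e1 difference was -0.92 without the 3 arrays with markers of other tissues.

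By fixed list, cell cycle genes rose together in wildtype mice: of 35 measured, 32 rose and 3 did not pass (32 higher adjusted over the list alone, camera adjusted p = 3.53e-26, adjusted p = 0.0347 with an estimated correlation). Of 30 acute phase genes, 18 rose and 12 did not pass (18 higher adjusted over the list alone, camera adjusted p = 1.46e-06, adjusted p = 0.320 with an estimated correlation). Among them were Lrg1, a secreted leucine-rich glycoprotein, at 2.24 ± 0.25, the iron-siderophore binding lipocalin Lcn2 at 1.73 ± 0.22, the protease inhibitor Serpina3n at 1.29 ± 0.13 and serum amyloid Saa3 at 1.56 ± 0.34. Of 26 extracellular matrix genes, 20 rose and 6 did not pass (20 higher adjusted over the list alone, camera adjusted p = 1.46e-06, adjusted p = 0.320 with an estimated correlation). Among them were elastin (Eln, 1.46 ± 0.15), fibronectin (Fn1, 0.95 ± 0.11) and the fibrillar collagen Col5a2 (0.85 ± 0.10). Of 16 goblet cell and mucin genes, 7 rose and 9 did not pass (9 higher adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.320 with an estimated correlation). Among them were the anion exchanger Slc26a4 (2.05 ± 0.20), the immunoglobulin transporter Pigr (1.17 ± 0.20) and the membrane mucin Muc1 (0.75 ± 0.092). Of 29 chemokine genes, 10 rose and 19 did not pass (10 higher adjusted over the list alone, camera adjusted p = 0.0400, adjusted p = 0.320 with an estimated correlation). Among them were Ccl17 (1.74 ± 0.24) and Ccl22 (0.65 ± 0.12), which attract T cells through the receptor CCR4, and the monocyte attractant Ccl2 (0.50 ± 0.10). For chemokines, the call was lost without wildtype air F2 (adjusted p = 0.0765), wildtype ozone M2 (0.05005) and wildtype ozone F1 (0.0771), in a range of 0.000352 to 0.320 over the alternatives. The median of chemokines, 0.17, was 0.27 without wildtype ozone F2.

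Some markers of lymphocytes fell after ozone in wildtype mice. Of 22 T and NK cell genes, 12 fell and 10 did not pass (12 lower adjusted over the list alone, camera adjusted p = 0.000105, adjusted p = 0.695 with an estimated correlation). Those that fell included the NK receptor Klrd1 (-1.04 ± 0.18), the cytokine receptor Il7r (-0.77 ± 0.15), and perforin (Prf1, -0.76 ± 0.12) and granzyme B (Gzmb, -0.62 ± 0.12), which kill target cells. Of 13 B and plasma cell genes, 5 fell and 8 did not pass (5 lower adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.810 with an estimated correlation). The B cell genes that fell included the antigen CD20 (Ms4a1) at -1.34 ± 0.44, adjusted p = 0.0257 and the inhibitory receptor Cd22 at -0.71 ± 0.24, adjusted p = 0.0293. For B and plasma cells, the call was lost without wildtype air F1 (adjusted p = 0.104), wildtype ozone F2 (0.0682) and the 3 arrays with markers of other tissues (0.0979), in a range of 0.00810 to 0.810 over the alternatives. With the dimmest genes left out, the calls of chemokines and B and plasma cells were lost. After another quantile normalization, the call of chemokines was lost. For Ms4a1, the call was lost without wildtype air M1 (adjusted p = 0.0548), wildtype air F1 (0.0858), wildtype ozone F2 (0.0896) and the 3 arrays with markers of other tissues (0.0988), in a range of 0.00830 to 0.360 over the alternatives. For Cd22, the call was lost without wildtype air M1 (adjusted p = 0.0553), wildtype air F1 (0.0963), wildtype ozone F2 (0.101) and the 3 arrays with markers of other tissues (0.112), in a range of 0.00810 to 0.447 over the alternatives. Of the antioxidant genes, Gclc, the catalytic subunit of glutathione synthesis, rose by 0.69 ± 0.092 and heme oxygenase (Hmox1) by 0.41 ± 0.082, the metallothionein Mt2 rose by 1.51 ± 0.26, and the quinone reductase Nqo1 stood at 0.11 ± 0.086, adjusted p = 0.338. The club cell secretory protein Scgb1a1 (0.0070 ± 0.047, adjusted p = 0.923) and surfactant protein C (Sftpc, 0.053 ± 0.043, adjusted p = 0.352) did not pass, nor did Il17a (0.087 ± 0.056). Il6 stood at 0.43 ± 0.19, adjusted p = 0.0904, and at 0.43 with adjusted p = 0.00108 without deficient ozone F2, in a range of 0.00108 to 0.470 over the alternatives. S100a8, an abundant neutrophil protein, was 13.68 on wildtype ozone M2 against 9.44 to 9.60 on the other 3 arrays of its group. Its difference was -0.37 ± 0.72, adjusted p = 0.722, and without that array it fell by 1.36 (adjusted p = 0.0295, range over the alternatives 0.0295 to 0.972). Other probe sets of the same gene stood apart for Top2a (0.13), Fbxo32 (-0.053), Pigr (0.057), Prf1 (0.072), Fn1 (0.28), 1 of 5 of Malat1 (-0.15) and 1 of 5 of Atrx (-0.027). Of the 4956 genes with several probe sets, 184 had probe sets called in both directions after ozone in wildtype mice and 93 in deficient mice.

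**Figure D1:**
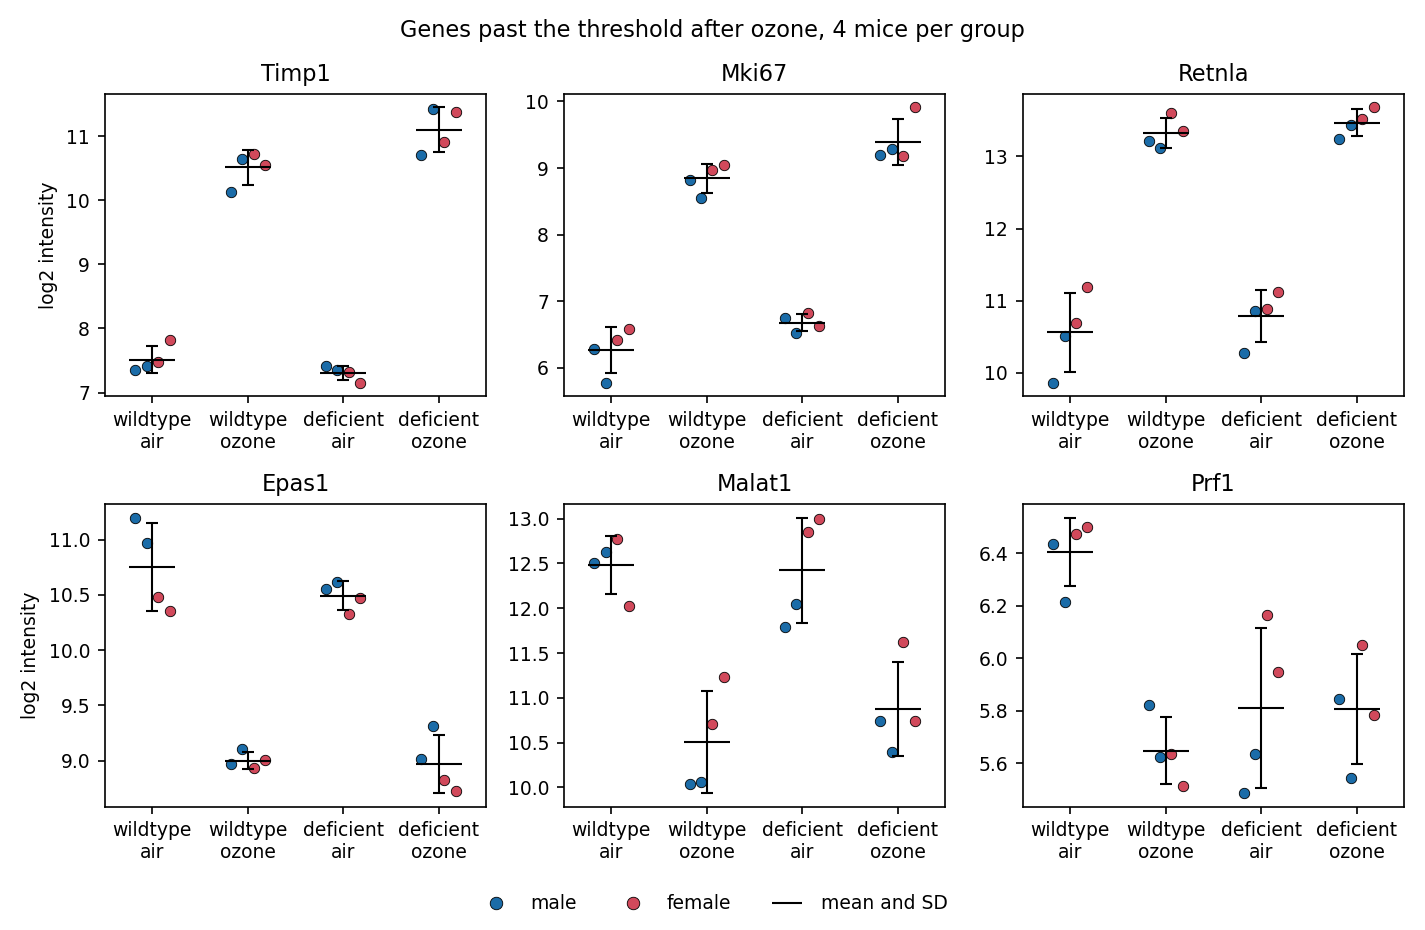
Log2 intensity of Timp1, Mki67, Retnla, Epas1, Malat1 and Prf1 on each of the 16 arrays, by group, with points coloured by sex and bars for the mean and SD of 4 mice. Timp1, Mki67 and Retnla lay higher, and Epas1 and Malat1 lower, after ozone in both genotypes, and Prf1 lay lower after ozone in wildtype mice.

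In adiponectin-deficient mice serum amyloid Saa3, an acute phase protein, rose 15.9-fold after ozone (3.99 ± 0.34 log2, n = 4 per group, adjusted p = 9.96e-07). Timp1 rose by 3.79 ± 0.16, Tnc by 3.31 ± 0.21 and Retnla by 2.69 ± 0.16. Birc5 rose by 2.95 ± 0.10 (adjusted p = 1.87e-10), Rrm2 by 2.84 ± 0.12, Cdk1 by 2.82 ± 0.14, Cep55, a protein of the final step of cell division, by 2.79 ± 0.11, Top2a by 2.75 ± 0.11 and Mki67 by 2.71 ± 0.14. Il6, an inflammatory cytokine, rose by 0.90 ± 0.19 (adjusted p = 0.00225) and the neutrophil attractant Cxcl1 by 0.92 ± 0.19, and neither ozone effect was shown to differ from that in wildtype mice (interaction adjusted p = 0.983 and 0.983). Without deficient ozone F2 the rises of Il6 and Cxcl1 were 0.62 and 0.69. Cxcl5, another neutrophil attractant, rose by 0.66 ± 0.21. For Cxcl5, the call was lost without deficient air F1 (adjusted p = 0.0578), the array labelled deficient air F2 (0.0844) and the 3 arrays with markers of other tissues (0.121), in a range of 0.0116 to 0.614 over the alternatives. The Cxcl5 difference was 0.33 without deficient ozone F2. In deficient air Il6 stood at 4.29 to 4.43, Cxcl5 at 4.26 to 4.47 and Cxcl1 at 4.80 to 5.27 log2 intensity. Eif2s3y, a Y-linked gene that females lack, read 4.11 to 4.46 on the female arrays. Il6 and Cxcl5 thus lay near the level of an absent transcript in air, which limits what the size of their rises means. Epas1 fell by 1.52 ± 0.11, Malat1 by 1.55 ± 0.25, Lrat by 1.61 ± 0.37 and Fbxo32 by 1.57 ± 0.25. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 2.23 ± 0.39, the carboxylesterase Ces1f by 1.52 ± 0.22 and Itih5, a hyaluronan-associated protein, by 1.41 ± 0.20. Car3, a carbonic anhydrase abundant in fat and muscle, fell by 2.61 ± 0.58, and stood at 13.44 on the array labelled deficient air F2 and 12.52 on deficient air M2. The Car3 difference was -1.65 without the 3 arrays with markers of other tissues. For Lrat, the call was lost without the 3 arrays with markers of other tissues and deficient ozone F2 (adjusted p = 0.0610), in a range of 0.00150 to 0.0794 over the alternatives. Over all genes, 3761 passed, 1954 higher and 1807 lower, with 130 and 45 of them moved at least 2-fold. The split turned to 3281 higher and 3358 lower over single probe sets, and to 48.3% higher without the 3 arrays with markers of other tissues. Without the 3 arrays with markers of other tissues and deficient ozone F2 the count was 2397, and both settings without these arrays were chosen after seeing the data.

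By fixed list in the deficient mice, of 35 cell cycle genes 33 rose and 2 did not pass (34 higher adjusted over the list alone, camera adjusted p = 1.42e-33, adjusted p = 0.0131 with an estimated correlation). Of 30 acute phase genes, 20 rose and 10 did not pass (24 higher adjusted over the list alone, camera adjusted p = 9.91e-12, adjusted p = 0.0397 with an estimated correlation). Among them were Serpina3n at 1.92 ± 0.13, Lcn2 at 1.80 ± 0.22 and ceruloplasmin (Cp) at 0.91 ± 0.095, whose 7 probe sets went both ways. Of 29 chemokine genes, 14 rose and 15 did not pass (14 higher adjusted over the list alone, camera adjusted p = 7.58e-05, adjusted p = 0.0397 with an estimated correlation). Among them were Ccl17 at 2.0 ± 0.24, Ccl22 at 1.14 ± 0.12 and Cxcl16 at 0.64 ± 0.087. Of 26 matrix genes, 19 rose and 7 did not pass (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.66e-08, adjusted p = 0.214 with an estimated correlation). Among them were type I collagen (Col1a1) at 1.60 ± 0.16 and elastin at 1.48 ± 0.15. Of 21 genes of matrix proteases and their inhibitors, 10 rose, 3 fell and 8 did not pass (10 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.118 with an estimated correlation). Members that rose included the membrane metalloproteinase Mmp14 at 1.10 ± 0.082 and macrophage elastase (Mmp12) at 1.17 ± 0.12. The median of proteases and inhibitors of matrix turnover, 0.39, was 0.24 without deficient air M2 and 0.26 without deficient ozone F2. Of 21 immediate early genes, 9 rose and 12 did not pass (9 higher adjusted over the list alone, camera adjusted p = 0.00310, adjusted p = 0.689 with an estimated correlation). Among them was the AP-1 subunit Junb at 1.23 ± 0.16. The median of immediate early genes, 0.29, was 0.47 without the 3 arrays with markers of other tissues. Of 16 goblet cell genes, 5 rose and 11 did not pass (5 higher adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.381 with an estimated correlation). Among them was Slc26a4 at 2.22 ± 0.20. The median of goblet cells and mucins, 0.18, was 0.27 without deficient ozone M2.

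Camera called 15 lists in the deficient mice at the preset correlation and 3 with an estimated correlation. Of 17 alveolar type 2 cell genes, 6 rose and 11 did not pass (6 higher adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.689 with an estimated correlation). Among them were the chitinase-like protein Chil1 at 0.70 ± 0.11 and surfactant protein D (Sftpd) at 0.33 ± 0.060. For alveolar type 2 cells and surfactant, the call was lost without deficient air M1 (adjusted p = 0.0592), deficient air M2 (0.135, with a median of 0.11) and deficient ozone M1 (0.0693), in a range of 0.00148 to 0.689 over the alternatives. Of 16 genes of the IL-17 response, 6 rose and 10 did not pass (6 higher adjusted over the list alone, camera adjusted p = 0.0389, adjusted p = 0.689 with an estimated correlation), led by Saa3, Lcn2 and Cxcl1, which other lists also hold. For genes of the IL-17 response, the call was lost without deficient air M1 (adjusted p = 0.127, with a median of 0.062) and deficient ozone F2 (0.0795, with a median of 0.052), in a range of 0.00991 to 0.689 over the alternatives. Of 19 club cell and xenobiotic enzyme genes, 1 rose, 7 fell and 11 did not pass (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.689 with an estimated correlation). Among them were the flavin monooxygenases Fmo2 at -1.10 ± 0.12 and Fmo1 at -0.75 ± 0.10, and the member that rose was haptoglobin (Hp), an acute phase protein, at 0.46 ± 0.077. For club cells and xenobiotic enzymes, the call was lost without deficient air M1 (adjusted p = 0.0523), deficient air M2 (0.0577, with a median of -0.087), the array labelled deficient air F2 (0.0569, with a median of -0.10) and the 3 arrays with markers of other tissues (0.115, with a median of -0.062), in a range of 0.00719 to 0.689 over the alternatives. The median of club cells and xenobiotic enzymes, -0.15, was -0.23 without deficient air F1. Of 17 circadian clock genes, 1 rose, 7 fell and 9 did not pass (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0374, adjusted p = 0.689 with an estimated correlation). Among them were the clock repressors Per2 at -1.18 ± 0.20 and Per3 at -0.99 ± 0.18 and the nuclear receptor Nr1d2 at -1.13 ± 0.17. For circadian clock genes, the call was lost without deficient air F1 (adjusted p = 0.0617), the array labelled deficient air F2 (0.0934), deficient ozone F1 (0.0685), deficient ozone F2 (0.0512) and the 3 arrays with markers of other tissues and deficient ozone F2 (0.0555), in a range of 0.00845 to 0.689 over the alternatives. The median of circadian clock genes, -0.23, was -0.36 without deficient air M2, -0.45 without deficient ozone M1, -0.37 without the 3 arrays with markers of other tissues and -0.54 with the dimmest genes left out. Of 22 T and NK cell genes, 1 rose, 3 fell and 18 did not pass (1 lower adjusted over the list alone, camera adjusted p = 0.462, adjusted p = 0.946 with an estimated correlation). The calls of alternative macrophage activation and of B and plasma cells were each lost without some single arrays and with an estimated correlation. With the dimmest genes left out, the calls of IL-17 response, B and plasma cells, proteases and inhibitors of matrix turnover, club cells and xenobiotic enzymes, goblet cells and mucins and adipocyte were lost.

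Adipocyte and striated muscle genes, markers of tissues beside the lung, were placed lower after ozone in the deficient mice by camera, calls that were lost without single arrays. Of 18 adipocyte genes, 4 fell and 14 did not pass (4 lower adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.689 with an estimated correlation). Among them was Thrsp, a regulator of fat synthesis, at -2.38 ± 0.71, adjusted p = 0.0195. For adipocyte genes, the call was lost without the array labelled deficient air F2 (adjusted p = 0.176, with a median of -0.42) and the 3 arrays with markers of other tissues (0.0618, with a median of -0.32), in a range of 0.000602 to 0.689 over the alternatives. For Thrsp, the call was lost without the array labelled deficient air F2 (adjusted p = 0.0697), deficient ozone F1 (0.0719) and the 3 arrays with markers of other tissues (0.0604, with a difference of -1.30), in a range of 0.00775 to 0.394 over the alternatives. Of 25 striated muscle genes, 4 fell and 21 did not pass (3 lower adjusted over the list alone, camera adjusted p = 0.00662, adjusted p = 0.689 with an estimated correlation). Among them was phospholamban (Pln) at -0.91 ± 0.23. For Pln, the call was lost without the 3 arrays with markers of other tissues and deficient ozone F2 (adjusted p = 0.103), in a range of 0.000952 to 0.103 over the alternatives. For striated muscle genes, the call was lost without deficient air M2 (adjusted p = 0.178, with a median of -0.081) and the 3 arrays with markers of other tissues (0.136, with a median of -0.14), in a range of 0.000402 to 0.689 over the alternatives. The muscle troponin Tnnt3 was 11.14 on deficient air M2 against 5.0 to 5.08 on the other deficient air arrays, and the squamous keratin Krt4 was 13.03 there against 5.64 to 6.35 on the other 15 arrays.

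**Figure D2:**
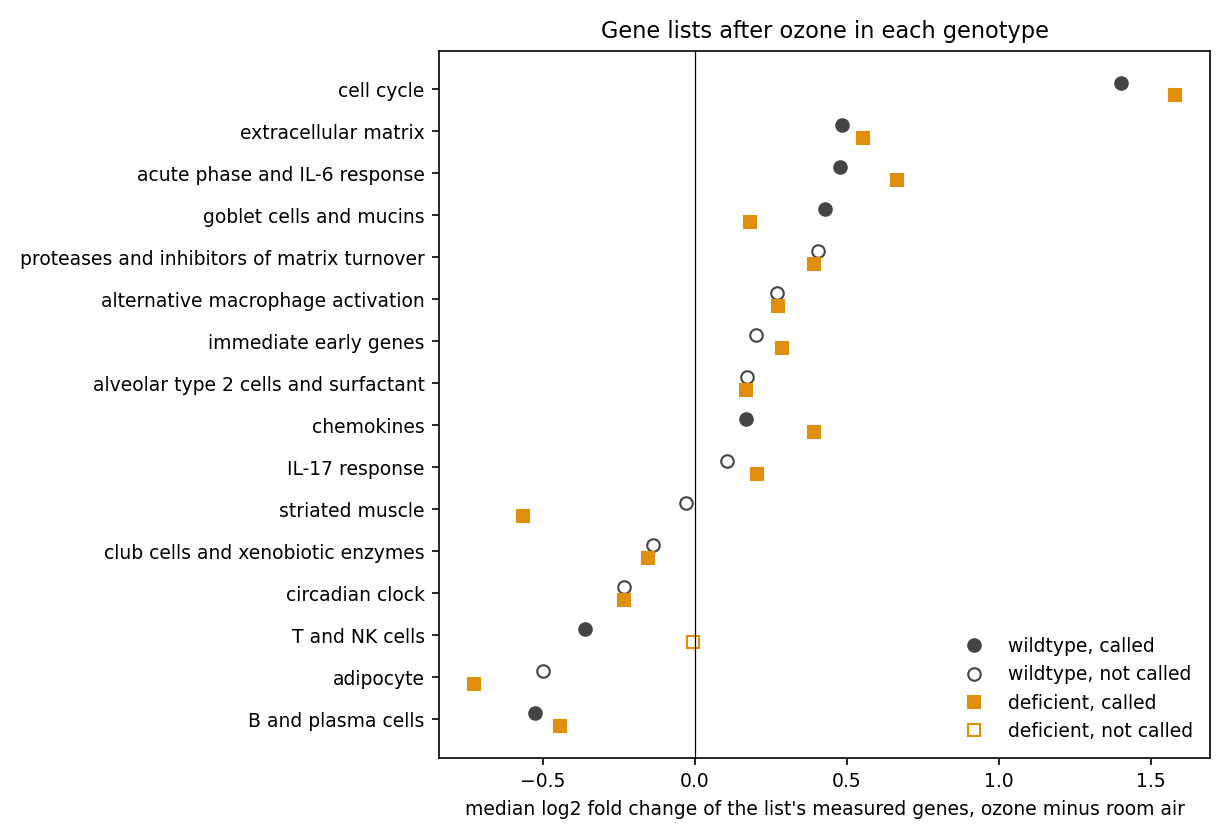
Median log2 fold change of ozone against room air over the measured genes of each fixed list called in either genotype, for wildtype mice (circles) and deficient mice (squares), with filled marks for lists past a camera adjusted p of 0.05 at the preset correlation. Cell cycle genes had the highest median in both genotypes, 1.40 and 1.58.

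The ozone responses of the genotypes were compared gene by gene. Of the genes that passed, 1532 rose and 1463 fell in both genotypes, where independent lists of those sizes would share 383 and 308. The count of genes passing in opposite directions was 0 by limma. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.862 and Spearman's rho of 0.833, and 97.7% of the 5312 genes that passed in either genotype had the same sign. The comparisons contrasted separate groups of arrays, but both came from the same fit of all arrays and shared its estimate of each gene's spread. Their calls are therefore not fully independent, and the counts given for independent lists can be too low. By the probe set tested for each gene, Timp1, Tnc, Retnla, Mki67, Birc5 and Slc26a4 were among the genes that rose in both. Epas1, Malat1, Lrat and Fbxo32 were among those that fell in both.

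The genotypes were compared in room air, without ozone. Clec16a, a gene of endosomal and autophagy pathways, was higher in the deficient mice, 1.57-fold (0.65 ± 0.063 log2, n = 4 per group, adjusted p = 0.000387), and was the 1 gene of 12393 that passed. For Clec16a the adjusted p was 0.104 in females alone, in a range of 9.36e-05 to 0.104 over the alternatives. Adipoq itself was -1.78 ± 0.58, adjusted p = 0.753 in the limma fit. At an unadjusted p under 0.05 there were 732 genes, against 619.65 by chance. The count was 2 without wildtype air F1 and 2 without deficient air F1. No other gene named here passed, among them Mki67 at 0.41 ± 0.14, the scavenger receptor Marco at 0.52 ± 0.22, Hmox1 at -0.24 ± 0.082 and Saa3 at -0.060 ± 0.34. Camera called 6 lists at the preset correlation, none of whose members passed, and 0 with an estimated correlation. It placed extracellular matrix genes lower, with a median of -0.16, none of the 26 past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 0.00078, adjusted p = 0.694 with an estimated correlation). Among them were Col4a2 at -0.28 ± 0.073 and Col1a1 at -0.45 ± 0.16. For extracellular matrix, the call was lost without the 3 arrays with markers of other tissues (adjusted p = 0.0931, with a median of -0.061), in a range of 4.37e-06 to 0.726 over the alternatives. It placed endothelial genes lower, with a median of -0.097, none of the 26 past the threshold and none adjusted over the list alone (camera adjusted p = 0.00100, adjusted p = 0.694 with an estimated correlation). The endothelin receptor Ednrb stood at -0.52 ± 0.16 and the lymphatic receptor Lyve1 at -0.32 ± 0.12. For endothelial genes, the call was lost without the 3 arrays with markers of other tissues (adjusted p = 0.127, with a median of -0.049), in a range of 1.32e-05 to 0.726 over the alternatives. The median of endothelial genes, -0.097, was -0.058 without the array labelled deficient air F2. Striated muscle genes were placed higher, with a median of 0.50, none of the 25 past the threshold and none adjusted over the list alone (camera adjusted p = 3.20e-08, adjusted p = 0.694 with an estimated correlation), the group in which deficient air M2 carried Tnnt3 at 11.14. For striated muscle genes, the call was lost without deficient air M2 (adjusted p = 0.0972, with a median of 0.092), in a range of 2.22e-11 to 0.726 over the alternatives. The median of striated muscle genes, 0.50, was 0.23 without wildtype air M1 and 0.20 without the 3 arrays with markers of other tissues. Its other calls, of alveolar type 1 and type 2 cells and oxidative phosphorylation, were each lost without some single arrays. With the replicate block, the call of alveolar type 2 cells and surfactant was lost. The number of lists was 12 without wildtype air F1, 2 without deficient air M2 and 10 without the array labelled deficient air F2.

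The genotypes were then compared after ozone, the question of the series. Clec16a was again higher in the deficient mice (0.72 ± 0.063 log2, n = 4 per group, adjusted p = 0.000106), and Saa3 was higher 5.16-fold (2.37 ± 0.34, adjusted p = 0.0270). Saa3 was 11.33 ± 0.97 in deficient and 8.97 ± 0.35 in wildtype mice after ozone (mean ± SD, n = 4), with the highest value, 12.73, on deficient ozone F2. For Saa3, the call was lost without wildtype air M1 (adjusted p = 0.0561), wildtype air F2 (0.0643), wildtype ozone M1 (0.0623), wildtype ozone F1 (0.114), wildtype ozone F2 (0.0960) and deficient ozone M1 (0.0805), in a range of 0.00202 to 0.508 over the alternatives. For Clec16a it was 0.0652 in males alone, in a range of 4.17e-05 to 0.0652. These were the 2 genes that passed, with 1392 at an unadjusted p under 0.05 against 619.65 by chance. The count was 1 without wildtype air M1, wildtype air F2, wildtype ozone M1, wildtype ozone F1 or wildtype ozone F2, 4 without wildtype air F1 or the array labelled deficient air F2, 5 without deficient air M2 and 7 without deficient ozone F1. Below the threshold, Birc5 stood at 0.59 ± 0.10, adjusted p = 0.0674 and at adjusted p = 0.0426 without wildtype air M2 (range over the alternatives 0.00420 to 0.561). Cd3g, a subunit of the T cell receptor complex, stood at 0.78 ± 0.16, adjusted p = 0.127 and at adjusted p = 0.0170 without deficient ozone M2 (range 0.0170 to 0.508). The adiponectin-binding cadherin Cdh13 was -0.55 ± 0.12, adjusted p = 0.143, Adipoq -1.82 ± 0.58, adjusted p = 0.280 (adjusted p = 0.0232 without the 3 arrays with markers of other tissues, range 0.0195 to 0.899), and Il6 0.50 ± 0.19, adjusted p = 0.347, with an Il6 difference of 0.22 without deficient ozone F2.

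Camera called 10 lists between the genotypes after ozone at the preset correlation and 0 with an estimated correlation. MHC class II genes were placed higher in the deficient mice, with a median of 0.33, none of the 12 past the threshold and 6 higher adjusted over the list alone (camera adjusted p = 5.93e-08, adjusted p = 0.267 with an estimated correlation). The class II chains H2-Ab1, H2-Eb1 and H2-Aa stood at 0.60 ± 0.13, 0.58 ± 0.11 and 0.42 ± 0.091. Cell cycle genes were placed higher, with a median of 0.23, none of the 35 past the threshold and 10 higher adjusted over the list alone (camera adjusted p = 4.99e-13, adjusted p = 0.261 with an estimated correlation). Among them were Mki67 at 0.54 ± 0.14 and Bub1, a mitotic checkpoint kinase, at 0.45 ± 0.12. T and NK cell genes were placed higher, with a median of 0.15, none of the 22 past the threshold and 5 higher adjusted over the list alone (camera adjusted p = 1.49e-05, adjusted p = 0.516 with an estimated correlation). Among them was Il7r at 0.49 ± 0.15. The median of T and NK cells, 0.15, was 0.23 without wildtype ozone M1, 0.083 without wildtype ozone F2, 0.099 without deficient ozone F1 and 0.34 with the dimmest genes left out. Acute phase genes were placed higher, with a median of 0.12, 1 of 30 past the threshold and 2 higher adjusted over the list alone (camera adjusted p = 0.00097, adjusted p = 0.466 with an estimated correlation). Among them was Timp1 at 0.59 ± 0.16 beside Saa3. The median of acute phase genes, 0.12, was 0.079 without wildtype ozone M1, 0.19 without wildtype ozone M2 and 0.21 without deficient ozone F1. Alveolar type 1 genes were placed lower, with a median of -0.16, none of the 9 past the threshold and 5 lower adjusted over the list alone (camera adjusted p = 0.00097, adjusted p = 0.366 with an estimated correlation). Among them was Emp2, a membrane protein of these cells, at -0.20 ± 0.067. Chemokine genes were placed higher, with a median of 0.16, none of the 29 past the threshold and none adjusted over the list alone (camera adjusted p = 0.00280, adjusted p = 0.261 with an estimated correlation). Among them was the B cell attractant Cxcl13 at 0.90 ± 0.32. Immediate early genes were placed higher, with a median of 0.21, none of the 21 past the threshold and none adjusted over the list alone (camera adjusted p = 0.00262, adjusted p = 0.516 with an estimated correlation). For chemokines, the call was lost without wildtype ozone F2 (adjusted p = 0.0831) and deficient ozone F2 (0.0687), in a range of 9.33e-05 to 0.261 over the alternatives. The median of chemokines, 0.16, was 0.051 without deficient ozone M2. For immediate early genes, the call was lost without deficient ozone F2 (adjusted p = 0.0716), in a range of 0.000309 to 0.516 over the alternatives. The calls of the IL-17 response, complement and fatty acid oxidation were also lost without some single arrays. With the dimmest genes left out, the calls of chemokines, IL-17 response, complement, fatty acid oxidation and immediate early genes were lost, and of the 10 lists then called 4 were higher and 6 lower. After another quantile normalization, the call of fatty acid oxidation was lost. The number of lists was 16 without wildtype ozone M2.

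**Figure D3:**
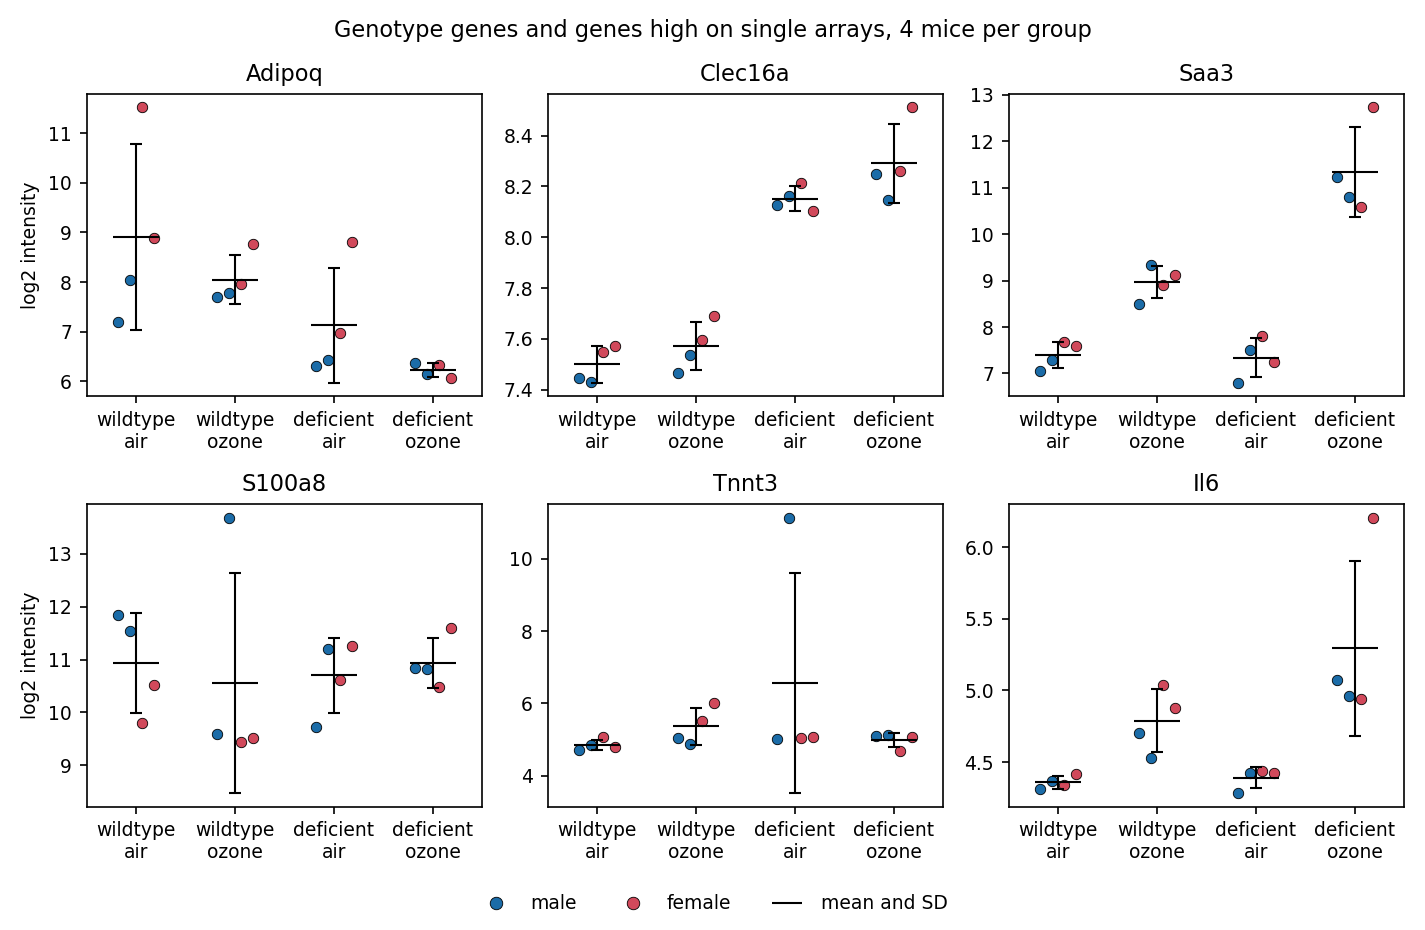
Log2 intensity of Adipoq, Clec16a, Saa3, S100a8, Tnnt3 and Il6 on each of the 16 arrays, by group, with points coloured by sex and bars for the mean and SD of 4 mice. All 8 deficient arrays lay above all 8 wildtype arrays for Clec16a, while S100a8 was highest on wildtype ozone M2 (13.68), Tnnt3 on deficient air M2 (11.14) and Il6 on deficient ozone F2 (6.21).

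Whether the ozone effect differed between the genotypes was tested by the interaction. Saa3 had the largest difference among the genes named, 2.43 ± 0.48 log2 (n = 4 per group, adjusted p = 0.673), and did not pass. The count of genes past the threshold was 0 by limma, with 605 at an unadjusted p under 0.05 against 619.65 by chance. The next smallest p-values belonged to Mbd4, a DNA glycosylase, at 0.52 ± 0.11, Kank2, a cytoskeletal adaptor, at 0.48 ± 0.10, Aaas, a nuclear pore protein, at 0.45 ± 0.10, and Leng1 at 0.38 ± 0.082, none past the threshold. Camera called 12 lists at the preset correlation and 0 with an estimated correlation, and fry called 0. Camera placed the ozone difference of T and NK cell genes higher in deficient than in wildtype mice, with a median of 0.25, none of the 22 past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 1.58e-08, adjusted p = 0.398 with an estimated correlation). Among them were Prf1 at 0.75 ± 0.17 and Gzmb at 0.51 ± 0.17. As given above, another probe set of Prf1 did not show its fall after ozone in wildtype mice. Prf1 already stood lower in deficient mice in air, at 5.49 to 6.16 against 6.21 to 6.50 log2 intensity in wildtype mice. After ozone its levels overlapped, at 5.54 to 6.05 in deficient and 5.51 to 5.82 in wildtype mice. It placed cell cycle genes the same way, with a median of 0.15, none of the 35 past the threshold and none adjusted over the list alone (camera adjusted p = 1.44e-07, adjusted p = 0.363 with an estimated correlation). MHC class II genes were also placed higher, with a median of 0.25, none of the 12 past the threshold and none adjusted over the list alone (camera adjusted p = 0.000161, adjusted p = 0.518 with an estimated correlation). Acute phase genes were too, with a median of 0.17, none of the 30 past the threshold and 3 higher adjusted over the list alone (camera adjusted p = 2.20e-05, adjusted p = 0.363 with an estimated correlation). Among them were Serpina3n at 0.63 ± 0.18 and Timp1 at 0.79 ± 0.22. The median of acute phase genes, 0.17, was 0.10 without deficient ozone M2. Striated muscle genes were placed lower, with a median of -0.48, none of the 25 past the threshold and none adjusted over the list alone (camera adjusted p = 2.25e-05, adjusted p = 0.647 with an estimated correlation), beside Tnnt3 at 11.14 on deficient air M2. The median of striated muscle genes, -0.48, was -0.21 without wildtype air M1, -0.090 without deficient air M2 and -0.21 without the 3 arrays with markers of other tissues. The other lists, of chemokines, the IL-17 response, interferon-stimulated genes, complement, matrix proteases, endothelium and immediate early genes, each lost their call without some single arrays. With the dimmest genes left out, the calls of chemokines, complement, proteases and inhibitors of matrix turnover and endothelium were lost. After another quantile normalization, the call of complement was lost. The number of lists was 7 without wildtype ozone F2.

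Both sexes were in every group, so males and females were compared over all groups, 8 against 8. The X inactivation RNA Xist was lower in males (-3.86 ± 0.098 log2) and the Y-linked genes Eif2s3y (3.37 ± 0.061), Uty (1.88 ± 0.16) and Kdm5d (1.86 ± 0.11) higher. Alas2, the erythroid enzyme of heme synthesis, was higher in males by 1.31 ± 0.12 (adjusted p = 2.15e-05) and the red cell anion exchanger Slc4a1 by 1.20 ± 0.21. The airway mucin Muc5b was lower in males (-1.05 ± 0.14, adjusted p = 0.000704), as were Pigr (-1.15 ± 0.14) and the clock repressor Nr1d1 (-1.06 ± 0.19). Over all genes, 701 passed, 316 higher and 385 lower in males, and with each array shifted to a common median the split was 273 higher and 506 lower. It turned to 442 higher and 379 lower with the mean of probe sets, 1223 higher and 853 lower over single probe sets, 74 higher and 67 lower at an adjusted p under 0.01 and 28 higher and 23 lower at a fold of at least 1.5. The count was 438 without wildtype air M1, 455 without wildtype air M2, 424 without wildtype air F1, 407 without deficient air F1, 451 without wildtype ozone F2 and 461 without deficient ozone M1. The 3' to 5' difference of Actb, a measure of RNA degradation, also went with sex, higher in both females than in both males of every group. It was 0.43 and 0.52 against 0.27 and 0.31 log2 in wildtype air, and 0.48 and 0.61 against 0.28 and 0.35 in deficient ozone. Gapdh separated the sexes in the same direction in all groups but deficient air. Whether RNA quality adds to the sex differences of genes and lists was not tested. Camera called 18 lists for sex at the preset correlation and 0 with an estimated correlation. Of 16 glucocorticoid response genes, 5 were higher and 11 did not pass (11 higher adjusted over the list alone, camera adjusted p = 3.74e-09, adjusted p = 0.160 with an estimated correlation). Of 16 goblet cell genes, 6 were lower and 10 did not pass (8 lower adjusted over the list alone, camera adjusted p = 4.28e-06, adjusted p = 0.0844 with an estimated correlation). Of 8 erythroid genes, 4 were higher and 4 did not pass (5 higher adjusted over the list alone, camera adjusted p = 3.89e-07, adjusted p = 0.0844 with an estimated correlation).

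Whether the ozone effect differed between the sexes was tested over both genotypes. The 1 gene that passed was Uty, a Y-linked histone demethylase, at -1.13 ± 0.13 log2 (2 arrays per sex and group, adjusted p = 0.0226), with 1072 genes at an unadjusted p under 0.05 against 619.65 by chance. Females lack Uty and stood at 4.04 to 4.32 over air and ozone, so its contrast only restates the level in males, 6.42 to 6.93 in air and 5.04 to 5.82 in ozone. It does not show an ozone response that differs between the sexes. For Uty, the call was lost without wildtype air F1 (adjusted p = 0.105), deficient air M2 (0.0658), the array labelled deficient air F2 (0.0509), deficient ozone M1 (0.0810), deficient ozone M2 (0.123), deficient ozone F1 (0.0577), deficient ozone F2 (0.126) and the 3 arrays with markers of other tissues (0.192), in a range of 0.00104 to 0.339 over the alternatives. The count of genes was 0 without wildtype air F1, deficient air M2, the array labelled deficient air F2, deficient ozone M1, deficient ozone M2, deficient ozone F1 and deficient ozone F2, 2 without deficient air F1, 3 without wildtype ozone M2, wildtype ozone F1 and wildtype ozone F2, 5 without wildtype air F2, 66 without wildtype ozone M1 and 133 without deficient air M1. Camera called 11 lists at the preset correlation and 0 with an estimated correlation. Circadian clock genes were placed higher, with a median of 0.31, none of the 17 past the threshold and 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000737, adjusted p = 0.188 with an estimated correlation). Genes of fatty acid and sterol synthesis were too, with a median of 0.26, none of the 21 past the threshold and 5 higher adjusted over the list alone (camera adjusted p = 0.000116, adjusted p = 0.398 with an estimated correlation). Wildtype air F1 and the array labelled deficient air F2, which carried fat markers, are both female air arrays. That list's mean deviation from all arrays was 0.31 and 0.39 log2 on them, against 0.070 on wildtype air F2 and 0.017 on deficient air F1. The lists for ozone by sex were not tested without these arrays.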

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

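The tests of tissue markers, RNA degradation, a wrong label, linked DNA, a probe variant, a single array and an estimated correlation were chosen for these patterns only after the results were seen, and the counts over other splits of the arrays were planned.

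The first pattern was genes of other tissues on 3 air arrays, for which fat and striated muscle carried over with the lung are candidate sources. The adipocyte list without Adipoq stood at least 1.32 log2 (median) above the other arrays of the group on wildtype air F1 and the array labelled deficient air F2, with Fabp4 at 11.78 against 8.37 to 9.44 and 12.26 against 9.31 to 9.64, and the striated muscle list 0.60 above them on deficient air M2, with Acta1 at 13.08 against 5.81 to 6.12. Of the members, 9 of 17 adipocyte and 13 of 25 muscle genes were brighter than the median gene on the other 13 arrays, and 4 adipocyte and 0 muscle genes were in another list. The tables argue against RNA degradation, since 0 of the 3 arrays lay outside the range of the other 13 for the 3' to 5' difference of Actb (0.27 to 0.62 log2) or Gapdh (-0.085 to 0.41). They also argue against a wildtype mouse under the label deficient air F2, where Clec16a lay 0.41 log2 above the highest wildtype array. Clec16a was picked from these data with that array among them. Without the 3 arrays it was still the 1 gene called for genotype in room air. On the deficient ozone arrays it stood at 8.14 to 8.51, also above every wildtype array. Squamous epithelium stays open, since its list's median of 0.22 on deficient air M2 met the bound of 0.5 set for excluding it, and that bound was judged wrong after it was seen, because 4 of the 13 members not above 1 log2 are bright in lung and would hide a small share while 6 of 19 stood above 1, with Krt4 at 13.03 against 5.76 and Krt13 at 10.64 against 4.71. The second principal component placed deficient air M2 at -36.89 and the other arrays between -7.98 and 9.01. Among its most negative weights were the squamous genes Krtdap, Lor, Krt4 and Krt13 and the muscle genes Tnnc2 and Acta1. These weights come from the same data, so they keep squamous epithelium as a candidate source beside muscle without settling it. No biological explanation was tested.

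The pattern of Clec16a was its higher level in the deficient mice in both exposures, 8.10 to 8.51 on the 8 deficient arrays against 7.43 to 7.69 on the 8 wildtype arrays. Clec16a and Adipoq lie on chromosome 16, so DNA of another strain linked to the altered locus is a candidate explanation. Of the 50, 100 and 200 other genes that differed most, 5, 8 and 10 were on that chromosome against 1.66, 3.33 and 6.66 by chance (one-sided Fisher's exact p = 0.0248, 0.0183 and 0.131). For the 50, chromosome 5 held 8 (exact p = 0.0115), and after adjustment over the 20 chromosomes p was 0.248 for chromosome 16 and 0.229 for chromosome 5, so these counts leave the explanation open. A sequence variant under the probes could not be tested with 1 probe set, and an effect of adiponectin deficiency on Clec16a itself was not tested apart from them.

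The pattern of lists between the genotypes was the 10 lists, immune and other, called after ozone, 9 of them higher in the deficient mice, while with the dimmest genes left out 5 of these calls remained and 4 of 10 lists were higher. Deficient ozone F2 carried high Il6 (6.21) and Cxcl1 (6.69), and 6 of the 10 lists kept their call and direction without that array, which argues against it as the whole cause. With an estimated correlation 0 of the 10 lists kept their call, as would follow if the genes of a list varied together from mouse to mouse, which is a candidate explanation. Fry, which does not compare a list with other genes, also called 0. A difference in the response to ozone that depends on adiponectin stays open and untested beyond the interaction, in which limma called 0 genes, with 605 at an unadjusted p under 0.05 against 619.65 by chance.

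Other splits of the same arrays were counted for each result. After ozone in wildtype mice 4546 genes were called against at most 1 in the other splits (1 of 35 splits as large). In deficient mice it was 3761 against at most 1 (1 of 35). Both shares lie under 0.05, but they are the smallest possible and were not adjusted for the other counts tested. The other splits mix air and ozone arrays, which widens the spread and holds their counts down. The size of the margin is therefore no measure of how far chance is excluded. The same limits hold for the sex difference, 701 against at most 27 (1 of 100), where other splits mix the sexes. For the overlap of the ozone responses, 2995 against at most 0 (1 of 100), the splits test nothing beyond those counts, since with so few genes called in another split their overlap is bound to be near 0. For genotype in ozone the count was 2 against at most 1 (1 of 35, the smallest share possible). That share lies under 0.05, but it rests on a margin of 1 gene and was not adjusted for the other counts tested. The count was 1 when any of 5 single arrays was left out, so chance is not firmly excluded. Chance cannot be excluded for the count of genotype in air, 1 against at most 1 (3 of 35). The interaction called 0 genes, so every split is bound to be as large (100 of 100, at most 1) and the splits test nothing there. For ozone by sex chance cannot be excluded either, 1 against 777 (12 of 100). The split with 777 genes turned the sexes over on all ozone arrays, which makes the contrast a sex difference, and the next highest count was 63, a check made after the count was seen. For the number of lists called, chance cannot be excluded in any of the 5 comparisons tested: 7 against at most 15 for ozone in wildtype mice (29 of 35), 15 against at most 20 for ozone in deficient mice (9 of 35), 6 against at most 17 for genotype in air (25 of 35), 10 against at most 17 for genotype in ozone (22 of 35) and 12 against at most 20 for the interaction (32 of 100). Some other splits keep most arrays of a group together and so carry part of a real difference, such as the ozone effect. Their counts are then not a measure of chance alone, and the splits do not show that the lists called after ozone arose by chance.

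Single arrays lay apart from the other 3 of their group by Dixon's test at the 95% level in 51 of 892 tests over 42 list scores, 178 named genes and 3 array summaries, where chance gives 44.6. The number is near that of chance, so most of the values listed here can be chance. The test measures a gap against the range of the group, so small gaps, also of dim genes, are among them. Deficient air M2 had 10 of the 51. Values are log2 intensities of genes, and for list scores the list's mean log2 deviation from the mean of all arrays. On deficient air M2, the values apart from its group were the metallothioneins list score at 0.99 against -0.43 to -0.36, the p53 targets list score at 0.20 against -0.11 to -0.084, the basal and squamous epithelium list score at 0.98 against -0.39 to -0.37 and the striated muscle list score at 2.0 against -0.047 to 0.081. Deficient air M2 stood apart for Arg1 at 6.99 against 5.33 to 5.47, Csrp3 at 10.57 against 9.21 to 9.30, Ier3 at 11.11 against 11.34 to 11.38 and Nusap1 at 6.06 against 5.85 to 5.89. Apart from their group on deficient air M2 were Sprr1a at 9.36 against 5.22 to 5.53 and Tnnt3 at 11.14 against 5.0 to 5.08. On deficient ozone F2, the values apart from its group were the fatty acid oxidation list score at -0.20 against 0.13 to 0.15, Col1a1 at 11.95 against 11.35 to 11.45, Cxcl1 at 6.69 against 5.69 to 5.85 and Il6 at 6.21 against 4.94 to 5.07. Deficient ozone F2 stood apart for Mgl2 at 7.35 against 7.76 to 7.80 and Mki67 at 9.91 against 9.18 to 9.28. Apart from their group on wildtype ozone F2 were C1qa at 8.38 against 8.97 to 9.08, C1qb at 7.92 against 8.88 to 8.94, Ccn1 at 10.95 against 10.49 to 10.57 and Cd22 at 7.43 against 8.11 to 8.16. On wildtype ozone F2, the values apart from its group were Kif20a at 6.29 against 6.03 to 6.06 and Ms4a1 at 6.28 against 7.45 to 7.59. Wildtype ozone M2 stood apart for the neutrophil list score at 2.72 against -0.43 to -0.35, the IL-17 response list score at 0.58 against -0.19 to -0.11, Adipor1 at 11.22 against 10.78 to 10.82 and Angptl4 at 8.93 against 7.88 to 7.91.

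Apart from their group on wildtype ozone M2 were Mt2 at 10.99 against 9.69 to 9.86 and S100a8 at 13.68 against 9.44 to 9.60. On wildtype ozone F1, the values apart from its group were Ccl17 at 9.85 against 8.91 to 9.05, Cxcl1 at 5.91 against 5.16 to 5.27, Slc26a4 at 8.41 against 7.19 to 7.30 and Ube2c at 8.77 against 8.87 to 8.89. The array labelled deficient air F2 stood apart for the alternative macrophage activation list score at -0.023 against -0.30 to -0.27, the thymus and lymphoid tissue list score at 0.17 against -0.062 to -0.033 and Kif20a at 4.88 against 4.74 to 4.76. Apart from their group on deficient air F1 were the club cells and xenobiotic enzymes list score at -0.038 against 0.12 to 0.15, Eln at 9.54 against 8.97 to 9.02 and Il17a at 5.72 against 5.88 to 5.91. On deficient ozone F1, the values apart from its group were Emp2 at 13.09 against 12.88 to 12.92, Lcn2 at 11.65 against 12.39 to 12.47 and Tnnt3 at 4.70 against 5.06 to 5.11. Wildtype air F1 stood apart for the thymus and lymphoid tissue list score at 0.17 against -0.11 to -0.087, Col1a1 at 10.91 against 10.20 to 10.28 and Saa1 at 4.48 against 4.62 to 4.65. Apart from their group on deficient air M1 were Il6 at 4.29 against 4.43 to 4.43 and Junb at 7.30 against 7.84 to 7.90. On deficient ozone M2, the values apart from its group were Cd3d at 7.07 against 7.75 to 7.89 and Nr1d1 at 8.05 against 8.79 to 8.92. Wildtype air F2 stood apart for Ccl5 at 8.74 against 9.0 to 9.06. Apart from its group on wildtype air M2 was Cyp1a1 at 9.67 against 10.41 to 10.52. On wildtype ozone M1, the value apart from its group was Cdk1 at 9.44 against 9.01 to 9.06.

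Uty passed the test of ozone by sex at -1.13 log2 (limma's adjusted p = 0.0226), but females lack this Y-linked gene, so the value restates its level in males and shows no difference in response between the sexes. Camera called 12 lists in the interaction of genotype and ozone at the preset correlation, a number for which chance cannot be excluded. Their medians were 0.087 for chemokines, 0.088 for IL-17 response, 0.17 for acute phase and IL-6 response, 0.14 for interferon-stimulated genes, 0.13 for complement, 0.25 for antigen presentation MHC class II, 0.25 for T and NK cells, 0.15 for cell cycle, 0.10 for proteases and inhibitors of matrix turnover, 0.082 for endothelium, 0.20 for immediate early genes and -0.48 for striated muscle, and none was called with an estimated correlation or by fry. Outside the comparisons, 389 of 2246 probe sets with no single gene name were called in the same direction after ozone in both genotypes.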

How the results depend on the processing

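The fits without arrays that carried other-tissue markers were chosen after the data were seen, and the other settings were planned. No call of a named gene or of a list reversed, by camera's direction for lists. The balance of higher against lower calls did turn in some settings given above, for ozone in each genotype, for sex and for the lists of genotype in ozone. The median of alveolar type 2 genes for genotype in air was 0.0098 without deficient air M2, and that of the IL-17 response in the interaction -0.030 without deficient air M1, against the sign with all arrays, and both calls were lost. Of 10756 values of named genes over the settings, 10446 kept their side of the threshold, 286 lost and 24 gained the call, and 166 that were not past the threshold in either setting changed sign. Of 1150 values of lists, 930 kept the call and 220 lost it. Signal over background is unknown, which limits the dim genes. Fits with each array left out keep 3 arrays in that group and, for ozone by sex, 1 array of a sex in it, which is assumed to vary like the other groups. Over them the genes called were 3750 to 4615 for ozone in wildtype mice, 2913 to 3822 for ozone in deficient mice, 1 to 2 for genotype in air, 1 to 7 for genotype in ozone, 0 for the interaction, 407 to 804 for sex and 0 to 133 for ozone by sex. Lists called were 6 to 13, 11 to 15, 2 to 12, 7 to 16 and 7 to 16 for the first 5 of these, the Adipoq difference -2.11 to -1.37 and the overlap 2483 to 2977. Fewer or more calls follow from the setting itself at adjusted p under 0.01 (2740 for ozone in wildtype and 2344 in deficient mice, 1 for genotype in ozone, 141 for sex, 0 for ozone by sex, 1853 in the overlap) and at a fold of at least 1.5 (780, 742 and 51 for ozone in wildtype mice, in deficient mice and sex). They do so too with every probe set on its own (8223, 6639 and 2076 for the same, 2 for genotype in air). With 2 arrays per group, males alone gave 1933 for ozone in deficient mice, 3 for genotype in air and 0 in ozone, and females alone 1927, 2495 and 1 for ozone in wildtype mice, in deficient mice and genotype in ozone. The cause was not tested for the following counts. For genotype in ozone they were 10 with array weights, 5 with the mean of probe sets, 5 after another quantile normalization and 1 with 8 groups, which gave 2 in air. Ozone by sex gave 0 with the dimmest genes left out and 0 with the mean of probe sets. Without the 3 arrays with other-tissue markers, 4330 genes were called for ozone in wildtype mice, 3093 in deficient mice, 9 for genotype in ozone and 0 for ozone by sex, with 3 lists for genotype in air. Without those and deficient ozone F2 the counts were 2397 for ozone in deficient mice, 5 for genotype in ozone, 298 for sex and 0 for ozone by sex. With an estimated correlation 1, 3, 0, 0 and 0 lists were called for ozone in wildtype mice, in deficient mice, genotype in air, in ozone and the interaction, and fry called 17 for ozone in wildtype mice and 0, 0 and 0 for the last 3. Within air the Adipoq difference was -1.78 (exact permutation p = 0.143), with fewer arrays. The replicate numbers did not pair the mice: over 12 pairs of groups within a sex, the correlation of the difference between replicates ran from -0.15 to 0.13, with 1 above 0.1 and 4 below 0. With the replicate block 4 genes were called for genotype in ozone, 4443 and 3699 for ozone in wildtype and deficient mice, 1 for genotype in air, 0 for the interaction, 685 for sex and 1 for ozone by sex. Lists for sex and ozone by sex were not run with arrays left out.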

Other observations

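The genotype difference averaged over both exposures, 8 deficient against 8 wildtype mice, was tested with limma after the data had been seen. It called 11 genes, and those named here were chosen after their values were seen. Besides Clec16a (0.69 ± 0.044 log2), the immunoglobulin A heavy chain Igha was higher in the deficient mice (1.84 ± 0.25, adjusted p = 0.0132), as were Ide, the insulin-degrading enzyme (0.77 ± 0.13), and the protocadherin Pcdhb3 (0.34 ± 0.060). The secreted phospholipase Pla2g1b (-0.60 ± 0.084), the phospholipid flippase Atp8a1 (-0.75 ± 0.12), the basement membrane collagen Col4a3 (-0.31 ± 0.053), the ubiquitin hydrolase Uchl1 (-0.38 ± 0.059), Ttc28 (-0.42 ± 0.060), Sec14l4 (-0.38 ± 0.054) and Spink4 (-0.29 ± 0.044) were lower. Pla2g1b, Ttc28, Uchl1 and Atp8a1 lie on chromosome 5 in the assembly GRCm38.p6. Of the 11 genes, only Clec16a and Spink4 had genotypes whose values did not overlap. Pcdhb3, Uchl1 and Spink4 were dim, with means per genotype between 4.83 and 5.81 log2 intensity. This averaged test was not repeated with arrays left out or under the other settings.

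Several lists that camera did not call held members that went both ways after ozone. Of 30 genes of the NRF2 antioxidant response, 8 rose and 4 fell in wildtype mice (8 higher and 4 lower adjusted over the list alone) and 8 rose and 6 fell in deficient mice (9 higher and 6 lower), with camera adjusted p of 0.517 and 0.901. Of 29 cytokine genes, 7 rose and 5 fell in wildtype mice (7 higher and 5 lower adjusted over the list alone) and 9 rose and 4 fell in deficient mice (10 higher and 4 lower), with camera adjusted p of 0.478 and 0.233. Of 11 p53 target genes, 4 rose and 2 fell in wildtype mice (4 higher and 2 lower adjusted over the list alone) and 4 rose and 2 fell in deficient mice (4 higher and 3 lower), with camera adjusted p of 0.583 and 0.712. Of 20 genes of fibroblasts, pericytes and smooth muscle, 4 rose and 5 fell in wildtype mice (4 higher and 5 lower adjusted over the list alone) and 4 rose and 6 fell in deficient mice (4 higher and 6 lower), with camera adjusted p of 0.856 and 0.875. Of 21 genes of fatty acid and sterol synthesis, 7 rose and 1 fell in wildtype mice (7 higher and 1 lower adjusted over the list alone) and 5 rose and 4 fell in deficient mice (5 higher and 4 lower), with camera adjusted p of 0.470 and 0.678.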
